A study of Mus musculus with 2 samples.

How the data were processed

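RNA was sequenced from EpCAM-positive epithelial cells taken from mouse breast tumours driven by the polyoma middle T oncogene (PyMT), and from tumours of the same model carrying a conditional knockout of Zeb1 (PyMT;Zeb1cKO). Each group has 1 library, so the comparison is between 2 libraries. Per the labels' protocols, RNA was extracted with a Trizol-type reagent, messenger RNA was enriched on oligo(dT) beads, and circularised libraries were read as DNA nanoballs. Whether a library holds 1 tumour or a pool, the strain of the mice, and the part of Zeb1 that was deleted are not given in the sources used here.

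The authors' deposited table of each library gives, per gene, an estimated count and an FPKM value (fragments per kilobase of gene length, scaled to the depth of the library). Per the file headers, the count is an expected count, the name that RSEM gives to its estimates. Per the submitters' processing notes, HISAT2 2.1.0, Bowtie2 2.2.5, RSEM 1.2.8 and DESeq are named with the mm10 genome build, without a stated role for each; the annotation is not given in the sources used here. Gene identifiers are Entrez numbers, together with unnamed gene models that hold 2.33% of the counts in the PyMT library and 2.68% in the knockout library. The deposited tables list genes with a value above 0, the lowest FPKM being 0.01. A gene missing from a table is described as not listed and is given no fold of its own, but it enters log2 ratios, medians and 2-fold counts at 0. This concerns 74 of the compared genes, of which 31 count as 2-fold higher and 43 as lower; at a floor of 3 counts, 18 and 33 would. Estimated counts that are not whole numbers (13.0% of genes in the PyMT library, 12.8% in the knockout library, within a tolerance of 1e-09) arise where reads fit more than 1 gene, and the ratios of such genes are uncertain.

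From these values the log2 ratio of each gene was computed as log2 of (FPKM in the knockout library + 1) over (FPKM in the PyMT library + 1), for the 12653 genes with an FPKM of at least 1 in at least 1 library. The pseudocount of 1 makes this ratio understate the difference of low genes. A count ratio was also computed, from the estimated counts rounded to whole numbers and divided by each library's total, knockout over PyMT, with an exact 95% interval (Clopper-Pearson, on the share of a gene's counts that fell in 1 library). These intervals cover counting error only. The depth was 21580274 estimated counts in the PyMT library and 21277484 in the knockout library. With 1 library per group there is no replicate check and no test between genotypes, so no p-value is given, and a 2-fold difference is a rule of size.

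Before the data were examined, 41 gene lists were fixed with 670 genes in all, of which 5 stand in more than 1 list. Of the 670, 639 were found in the deposited tables, 4 of them through a synonym. The mast cell list (7 genes) and the mitochondrially encoded list (13 genes) had no gene above the filter, which left 39 lists. For each list the median log2 ratio was set against 10000 random lists of the same size, matched on mean expression in 20 bins, and a list was said to stand apart when its median lay outside the central 95% of them. This percentile is a description of these libraries. The named genes were also chosen by a rule written beforehand. They are Zeb1, Cxcl1 and Epcam; the 10 genes with the highest and the 10 with the lowest log2 ratio among genes with an FPKM of at least 5 in the higher library, leaving out predicted models, antigen receptor segments, haemoglobins and pseudogenes; up to 2 members of each list with the highest and up to 2 with the lowest ratio; and, for lists of other cell types, the member with the highest value. Not every gene that the rule picks is reported here, and genes named outside the rule are said to be so. Coordinates are from the GENCODE annotation of GRCm38, the assembly that mm10 corresponds to, matched by symbol, and synonyms are from the RefSeq gene table of the same assembly.

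The steps were tested on simulated counts for the 12653 genes of this comparison. Of genes changed 3-fold, 91.0% passed 2-fold in the right direction, and of genes changed 6-fold, 98.0%. The counting intervals held the true ratio in 95.3% of cases, and 7.5% of unchanged lists of 20 genes fell outside the central range. The simulated counts carried counting error alone, with no difference between animals and no shared regulation within a list. These rates are therefore not error rates for the real libraries. Alternatives were another pseudocount (0.1), other scalings (a median ratio, TPM, and CPM with TMM factors from edgeR), other filters on low values, other fold thresholds, random lists matched also on gene length, and the removal of genes of other cell types, of genes with non-whole counts and of the H2 heavy chains. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for the TMM factors alone, were used.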

Results

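To find which signals from tumour cells could carry the effect of Zeb1 on M2-like tumour-associated macrophages, the transcriptomes of EpCAM-positive cells from PyMT tumours and from PyMT tumours with a conditional Zeb1 knockout were compared. Zeb1 is a transcription factor that represses epithelial genes and drives epithelial-mesenchymal transition (EMT). The PyMT library held 16162 listed genes and 21580274 estimated counts, and the PyMT;Zeb1cKO library 16206 genes and 21277484 estimated counts. The 10 most abundant genes took 5.42% of the counts in the former and 4.87% in the latter. There are no replicates, so genotype cannot be told apart from the tumour, animal or batch that each library came from, and all differences below are between these libraries.

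Zeb1 and Cxcl1 were both lower in the knockout library. Zeb1 (Entrez gene 21417, chromosome 18, 5591860 to 5775467, GRCm38) had 96 estimated counts in the PyMT library and 38 in the knockout library, a count ratio of 0.401 (95% counting interval 0.268 to 0.59). Its FPKM was below 1 in both, 0.79 against 0.32, so its log2 ratio of -0.44 depended on the pseudocount and was -1.08 with a pseudocount of 0.1. The count covers the whole gene, and reads inside and outside the deleted part are not separated. Fibroblast and endothelial markers were present in both libraries (Col1a1 at 230.8 and 258.9 FPKM, Plvap at 29.31 and 20.73). The cells that the Zeb1 and Cxcl1 reads came from are therefore not known. The paralog Zeb2, named after its values were seen, had an FPKM of 0.39 in both libraries. Cxcl1 (Entrez gene 14825, chromosome 5, 90891241 to 90893115), a chemokine that acts on the receptor Cxcr2, had 123 counts against 15, a ratio of 0.124 (0.0672 to 0.212), with FPKM of 7.36 and 0.89 and a log2 ratio of -2.15. Epcam (Entrez gene 17075, chromosome 17, 87635979 to 87651129), the surface protein used to isolate the cells, was at 740.8 FPKM in the PyMT library and 479.7 in the knockout library, a ratio of 0.653 (0.641 to 0.665).

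**Figure D1:**
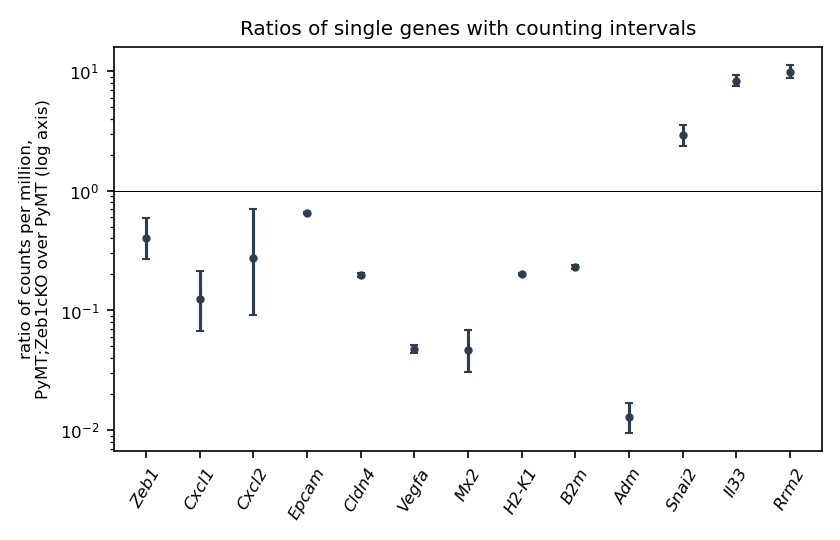
Count ratio (knockout over PyMT library, log axis) of 13 named genes, 1 library per group; bars are exact 95% intervals that cover counting error only. Cxcl1 lies at 0.124 and Zeb1 at 0.401, while Rrm2 lies at 9.88 and Il33 at 8.36.

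Across the transcriptome, 1291 genes were at least 2-fold higher and 1111 at least 2-fold lower in the knockout library, together 19.0% of the 12653 genes compared, and 10251 lay within 2-fold. Of the genes past 2-fold, 53.7% were higher, and 42.8% were higher after scaling by the median ratio. The median log2 ratio of all genes was 0.13 with the authors' scaling and 0.01 with the median ratio. The random lists share this offset, so list percentiles are relative to it. Of the 39 measured lists, 20 stood apart from random lists. The cell cycle list was the only higher one with the authors' scaling, and the 19 lower lists included glycolysis and hypoxia, interferon response, MHC class I presentation, acute phase, mesenchymal and cytokine genes.

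**Figure D2:**
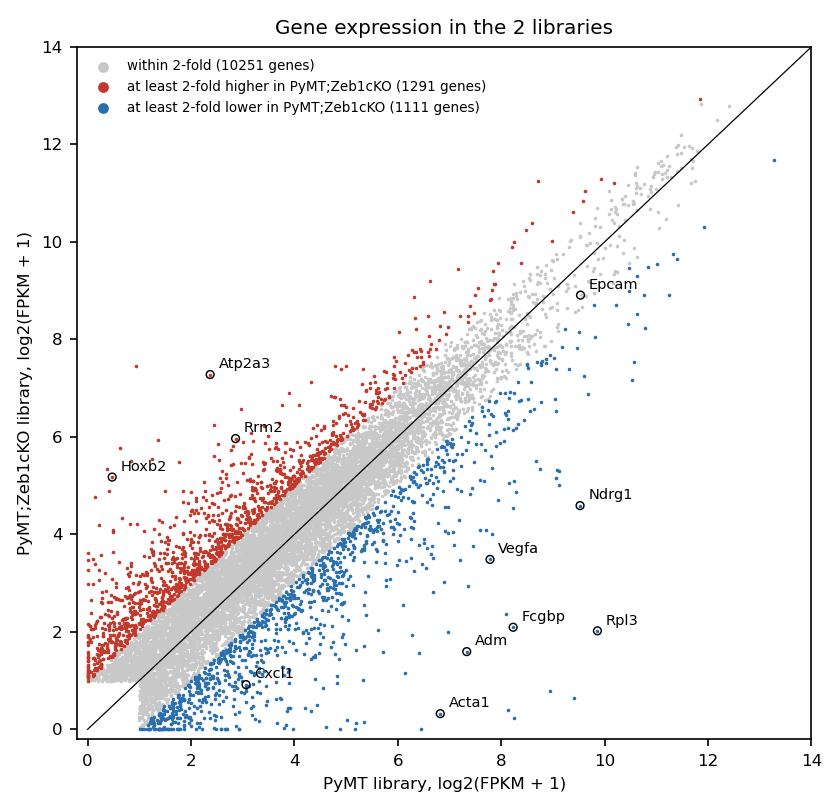
FPKM of each gene in the PyMT library (x axis) and in the knockout library (y axis), both on log2(FPKM + 1) scales, 1 library per group; the line marks equal values. Red points are the 1291 genes at least 2-fold higher in the knockout library, blue points the 1111 at least 2-fold lower, and grey points the 10251 within 2-fold.

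Mesenchymal genes were lower in the knockout library, while epithelial genes as a group did not stand apart. Of 20 measured mesenchymal genes, 9 were at least 2-fold lower and none was 2-fold higher on the log2(FPKM + 1) scale, with a median log2 ratio of -0.88, below all 10000 random lists. The calcium-binding protein gene S100a4 went from 25.04 FPKM in the PyMT library to 2.22 in the knockout library, with a count ratio of 0.0927 (0.0519 to 0.155). Vim, named after its values were seen, was at 269.5 and 88.4. N-cadherin (Cdh2) was low and higher in the knockout library, at 0.29 and 1.26, with a count ratio of 4.41 (2.92 to 6.85). Endothelial marker genes were also lower as a group, with a median of -0.61. Fibroblast genes went both ways (9 lower and 6 higher), with a median of -0.35 that no longer stood apart with random lists matched on length (2.54). The mesenchymal ratios are not separated from these cells. Selection for EpCAM should remove such cells, but their markers were present in both libraries. The 33 epithelial junction and identity genes had a median of -0.08, at percentile 8.96, with 1 gene 2-fold higher and 3 lower. Among them the desmosomal cadherin Dsc2 was higher, at 4.41 and 15.28 FPKM, and the tight junction gene Cldn4 lower, at 773.6 and 151.8. E-cadherin (Cdh1), a known target of Zeb1 repression, was at 133.5 and 92.96; it was named after its values were seen. The 9 measured EMT transcription factors had a median of -0.23, at percentile 11.28, and the 3 with an FPKM of at least 5 had a median of 0.52, at 81.28. Snai2 was higher in the knockout library (3.28 and 9.45 FPKM, ratio 2.91, 2.38 to 3.57), and Twist1 (3.58 and 1.58) and Prrx1 (1.86 and 0.62) were lower.

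Chemokines, and cytokines and mediators that act on macrophages, were lower as groups in the knockout library. Cxcl1 and its neighbour Cxcl2 (22 counts against 6, ratio 0.277, 0.0918 to 0.703) were the 2 measured members of the ELR CXC list, whose median of -1.43 lay at percentile 1.59. It lay inside the central range with random lists matched also on gene length (7.35), with a pseudocount of 0.1 (2.81), with TMM factors (4.72) and with either stricter filter, which left Cxcl1 alone (10.41 and 2.97). Of 21 other chemokines, 4 were 2-fold lower and 2 higher (1 higher with Xcl1 at a floor of 3 counts), with a median of -0.64 at percentile 0.04. Ccl5 went from 13.08 to 3.36 FPKM and Ccl9 from 5.34 to 1.03, while Ccl21a, a chemokine of lymphoid stroma, went from 0.21 to 5.45 and Xcl1 was listed in the knockout library alone, with 7 counts. Ccl5 and Ccl21a had non-whole counts, so their ratios are uncertain. Of 21 macrophage-acting cytokines and mediators, 11 were 2-fold lower and 1 higher, with a median of -1.10, below all random lists. Vegfa, the angiogenic growth factor, was at 219.4 FPKM in the PyMT library and 10.21 in the knockout library (ratio 0.0476, 0.0441 to 0.0513), and the prostaglandin E synthase gene Ptges at 25.77 and 2.45. The alarmin Il33 was the 1 member at least 2-fold higher, at 8.0 and 66.51 FPKM (ratio 8.36, 7.54 to 9.3). Of 11 immune ligands of tumour cells, 7 were 2-fold lower, with a median of -1.19, below all random lists. The galectins Lgals3 (284.3 and 32.32 FPKM) and Lgals9 (190.6 and 33.58) had the lowest log2 ratios, and Cd24a was at 314.9 and 455.6. Neutrophil marker genes were lower along with these groups, with a median of -2.58, whereas pan-leukocyte genes had a median of -0.05. Without a filter on low values these medians were smaller, at -0.49 for the ELR CXC list, -0.13 (percentile 1.59) for other chemokines, -0.50 for cytokines and mediators, -0.76 for immune ligands and -0.69 for neutrophil genes, and all still stood apart. Immediate-early genes (median -1.38) and glycolysis and hypoxia genes (median -1.86) were lower in the knockout library as well, and the chemokine and cytokine ratios are not separated from these.

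Proliferation genes were higher in the knockout library, and genes of glycolysis and the hypoxia response were lower. All 32 cell cycle genes were at least 2-fold higher, with a median log2 ratio of 2.42, above all 10000 random lists. Cyclin A2 (Ccna2) went from 4.43 to 47.71 FPKM (ratio 10.8, 9.53 to 12.4) and the ribonucleotide reductase subunit Rrm2 from 6.27 to 61.5 (ratio 9.88, 8.72 to 11.2), and the lowest log2 ratio was that of E2f1, at 1.18. Of 25 glycolysis and hypoxia genes, 19 were at least 2-fold lower, with a median of -1.86, below all random lists. Adm, which encodes the vasodilator adrenomedullin, went from 160.3 to 2.02 FPKM (ratio 0.0128, 0.00954 to 0.0168) and Ndrg1, a hypoxia-induced gene, from 736.4 to 23.09 (ratio 0.0315, 0.0298 to 0.0333). Pdk1, a kinase that restrains pyruvate entry into mitochondria, was higher, at 13.27 and 22.1. Gapdh and Eno1, named outside the rule, share reads with unnamed gene models or with Eno1b. With these copies added, the count ratio was 0.316 (0.313 to 0.32) for Gapdh and 0.534 (0.529 to 0.54) for Eno1. Immediate-early and dissociation-response genes were lower beside these groups, with a median of -1.38, below all random lists, and 10 of 18 members 2-fold lower. Their lowest members were Dusp1 (101.8 and 10.36 FPKM) and Ier3 (303.3 and 33.03), and the heat shock gene Hsph1 was higher (4.95 and 30.07). Skeletal muscle (median -3.82), neutrophil (-2.58) and endothelial genes (-0.61) were lower as well.

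**Figure D3:**
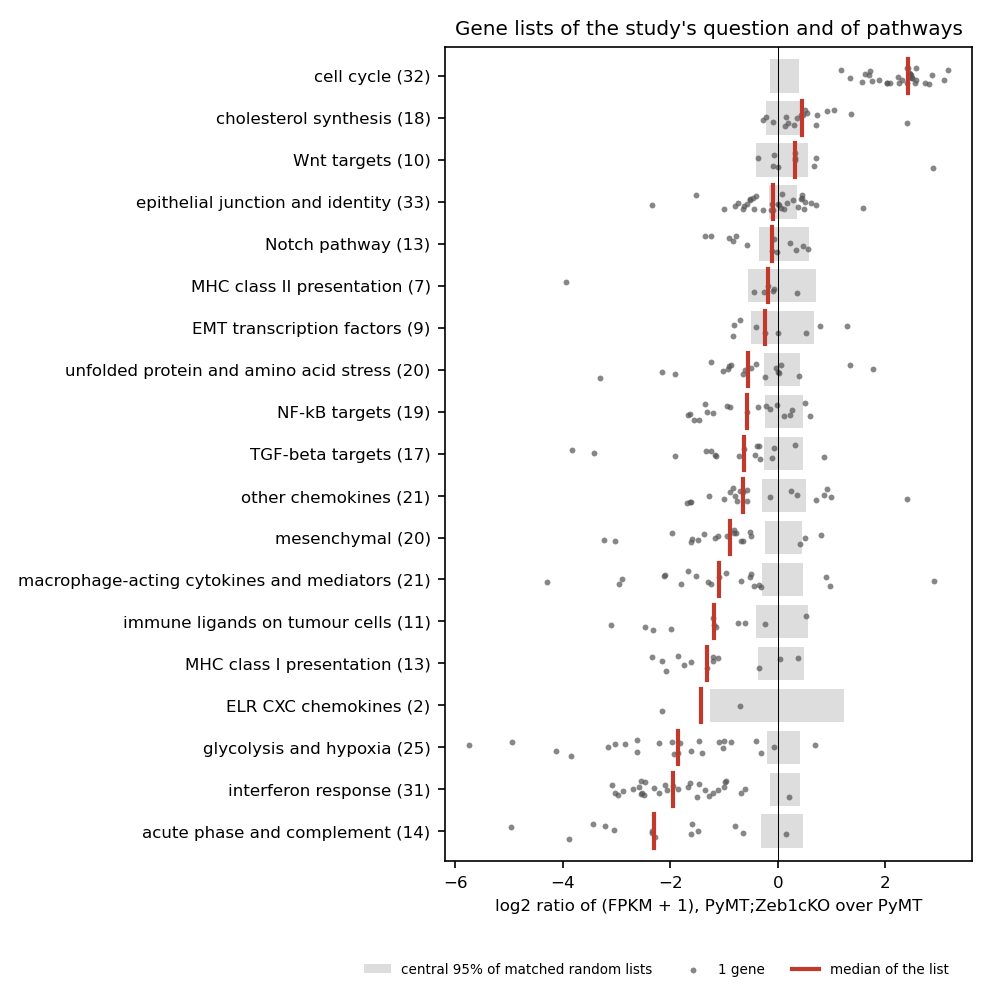
Median log2 ratio (knockout over PyMT library) of each study and pathway list (red line), with its measured members as small points and the central 95% of 10000 matched random lists as a grey bar. Cell cycle, at 2.42, lies above its bar, and acute phase, at -2.30, interferon response, at -1.95, and glycolysis and hypoxia, at -1.86, lie below theirs.

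Interferon-stimulated genes, the MHC class I pathway and acute phase genes were lower in the knockout library. Of 31 interferon response genes, 26 were at least 2-fold lower, with a median log2 ratio of -1.95, below all random lists. Mx2, an antiviral GTPase family gene annotated as a polymorphic pseudogene, went from 590 to 27 counts (ratio 0.0464, 0.0303 to 0.0682). Usp18, a brake on interferon signalling, went from 29.23 to 2.72 FPKM, whereas the RNA sensor gene Ifih1 was at 2.88 and 3.48. Of 13 MHC class I presentation genes, 10 were 2-fold lower, with a median of -1.31, below all random lists. The heavy chain H2-K1 was at 2425 and 481.8 FPKM (ratio 0.201, 0.197 to 0.204) and its light chain B2m at 1406 and 316.1 (ratio 0.23, 0.223 to 0.238). H2-K1 had non-whole counts, so its ratio is uncertain, while B2m had whole counts in both libraries. The peptide-trimming enzyme gene Erap1 was at 7.75 and 10.37. MHC class II genes did not stand apart, with a median of -0.18 at percentile 18.23. Within that list H2-Eb1 went from 659 to 13 counts (ratio 0.02, 0.0106 to 0.0345), while H2-DMa was at 161 and 153. Of 14 acute phase and complement genes, 11 were 2-fold lower, with a median of -2.30, below all random lists. Lbp, the lipopolysaccharide-binding protein gene, went from 530.8 to 34.88 FPKM (ratio 0.0661, 0.063 to 0.0694), and Steap4 was at 21.42 and 23.88. Neutrophil (median -2.58), endothelial (-0.61) and immediate-early genes (-1.38) were lower beside these groups.

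Targets of NF-kB and of TGF-beta, and genes of unfolded protein and amino acid stress, were also lower as groups, beside the lower immediate-early genes (median -1.38) and neutrophil genes (median -2.58). The 19 NF-kB targets had a median of -0.57 at percentile 0.02, with 7 genes 2-fold lower; Tnfaip2 was at 12.22 and 3.15 FPKM and Zc3h12a at 15.16 and 4.2, against 5.88 and 9.46 for Ripk2. The 17 TGF-beta targets had a median of -0.63 at percentile 0.02, with 7 genes 2-fold lower and 10 within 2-fold. Among the latter were Smad6 (log2 ratio -0.1) and Smad7 (-0.07), both named after their values were seen. Connective tissue growth factor (Ctgf) was at 556 FPKM in the PyMT library and 38.24 in the knockout library, and Cyr61 at 432.3 and 39.72. The 20 genes of unfolded protein and amino acid stress had a median of -0.55 at percentile 0.03, with 5 genes 2-fold lower, 2 higher and 13 within 2-fold, among them the chaperone genes Calr (log2 ratio 0.07) and Hsp90b1 (0.03), both named after their values were seen. Ddit3, which encodes the stress factor CHOP, was at 135.4 and 12.76 FPKM, and the serine synthesis enzymes Psat1 (38.67 and 134.9) and Phgdh (60.01 and 154.4) were higher. Cholesterol synthesis genes had a median of 0.46 at percentile 97.29, inside the central range with the authors' scaling and outside it with each of the other scalings; Idi1 was the member with the highest ratio, at 3.27 and 21.58 FPKM. Wnt targets (median 0.32, percentile 80.16) and Notch pathway genes (median -0.10, percentile 13.71) did not stand apart, although Notch genes did as lower with an FPKM of at least 5 (-0.58, 1.51) and with a mean FPKM of at least 1 and at least 20 counts (-0.34, 2.46). The secreted Wnt inhibitor Wif1 was higher, at 12.55 and 99.14 FPKM, and Notch4 (5.49 and 1.55) and Jag1 (5.75 and 1.86) were lower.

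Among mammary cell-state lists, luminal keratin and progenitor genes were lower in the knockout library, with a median of -1.20 below all random lists and 6 of 10 members 2-fold lower. Krt19 was at 280.9 and 91.44 FPKM and the surface mucin gene Muc1 at 14.08 and 30.82. Immediate-early (median -1.38), neutrophil (-2.58) and endothelial genes (-0.61) were lower beside this list. Milk and secretory genes split, with 6 of 13 members 2-fold higher and 3 lower. Their median was 0.06 (percentile 41.22) with the authors' scaling and -0.08 with the median ratio. It was -0.26 (percentile 1.37) without a filter on low values and 0.59 (98.96) for genes with a mean FPKM of at least 1 and at least 20 counts, so it turned with the filter. Lalba, which encodes alpha-lactalbumin, went from 4.86 to 45.3 FPKM, while the casein genes Csn1s1 (31.72 and 3.71) and Csn3 (2551 and 857.7) were lower. Luminal hormone-sensing genes had a median of -0.36 (percentile 6.0), with the luminal factor Gata3 at 38.88 and 85.86 FPKM and Ly6a at 191.8 and 16.03. Basal and myoepithelial genes had a median of 0.27 (percentile 74.98), with Igfbp5 at 245.1 and 760.9 and Krt17 at 181.7 and 67.1. The 5 measured genes of hair and skin keratinisation had a median of -0.76 (percentile 1.64), 0.03 without a filter on low values and -0.17 without genes with non-whole counts. The list also no longer stood apart with a pseudocount of 0.1 (4.03), with an FPKM of at least 5 (4.94) or with random lists matched on length (2.77).

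Markers of other cell types were present in both libraries. Pan-leukocyte genes (median -0.05, percentile 21.77) did not stand apart, and none of 10 was past 2-fold on the log2(FPKM + 1) scale. The lowest was Cytip, at 829 and 353 counts (ratio 0.432, 0.38 to 0.49), and Ikzf1 was at 17.31 and 28.03 FPKM. Macrophage genes had a median of 0.12 (percentile 48.44) with the authors' scaling, -0.01 with TMM factors and -0.02 with the median ratio. C1qa was at 148.5 and 105.0 FPKM, Cx3cr1 at 1.34 and 7.64, and Fcgr3 at 21.16 and 5.92. The 7 measured M2-associated macrophage genes had a median of -0.23 (percentile 21.36), and the 2 with an FPKM of at least 5 a median of 0.34 (64.9). Arg1, an arginase used as a marker of M2-like cells, was at 298.2 and 396.5 FPKM (ratio 1.34, 1.31 to 1.38). Chil3 went from 110 to 5 counts (ratio 0.0461, 0.0147 to 0.111). Mrc1 and Cd163 of the same list, named after their values were seen, were below an FPKM of 1 in both libraries. The cells that the Arg1 and Chil3 reads came from are not known, so neither ratio measures M2-like macrophages here. Neutrophil genes were lower, with a median of -2.58 below all random lists and 6 of 7 members 2-fold lower. This median is the value of Ngp, listed in the PyMT library alone with 106 counts and named after its values were seen, and so depends on the pseudocount. It was -4.17 with a pseudocount of 0.1, -0.69 without a filter on low values, and -2.39 with Ngp and Camp at a floor of 3 counts. S100a8 was at 225.8 and 14.99 FPKM and S100a9 at 39.1 and 1.03, and Camp was listed in the PyMT library alone, with 15 counts. Of these 7, Ltf (281.2 and 81.2), S100a8 and S100a9 are also made by epithelial cells. All 8 measured skeletal muscle genes were lower, with a median of -3.82 below all random lists; the actin gene Acta1 went from 3127 to 7 counts. Endothelial genes (median -0.61, percentile 0.3), with Flt1 at 8.61 and 1.47 FPKM, and fibroblast genes (median -0.35, percentile 1.64), with Postn at 128.5 and 33.19 and Col1a1 at 230.8 and 258.9, also stood apart, the fibroblast list no longer so with random lists matched also on length (2.54). T and NK cell genes (median -0.15, percentile 28.27), B and plasma cell genes (0.96, 95.36), dendritic cell genes (-1.0, 3.27), adipocyte genes (-0.18, 20.8) and erythroid genes (-0.53, 3.68) did not. Some of these calls turned on the settings. The 3 measured B and plasma cell genes stood apart as higher with a pseudocount of 0.1 (2.28, 98.78), and so did the 2 that pass either stricter filter, Jchain and Derl3 (1.83 each, 97.85 and 99.46). Erythroid genes stood apart as lower with a pseudocount of 0.1 (-0.78, 1.58) and without a filter (-0.44, 0.77), and dendritic cell genes with TMM factors (-1.38, 2.1) and without non-whole counts (-1.11, 2.42). Ribosomal protein genes (0.38, 97.12) and replication-dependent histones (-0.36, 2.88) did not stand apart either. With TMM factors the ribosomal median stood apart (0.27, 97.92), and the histone median stood apart as higher among genes with an FPKM of at least 5 (0.83, 98.28) and as lower without non-whole counts (-0.95, 1.52).

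**Figure D4:**
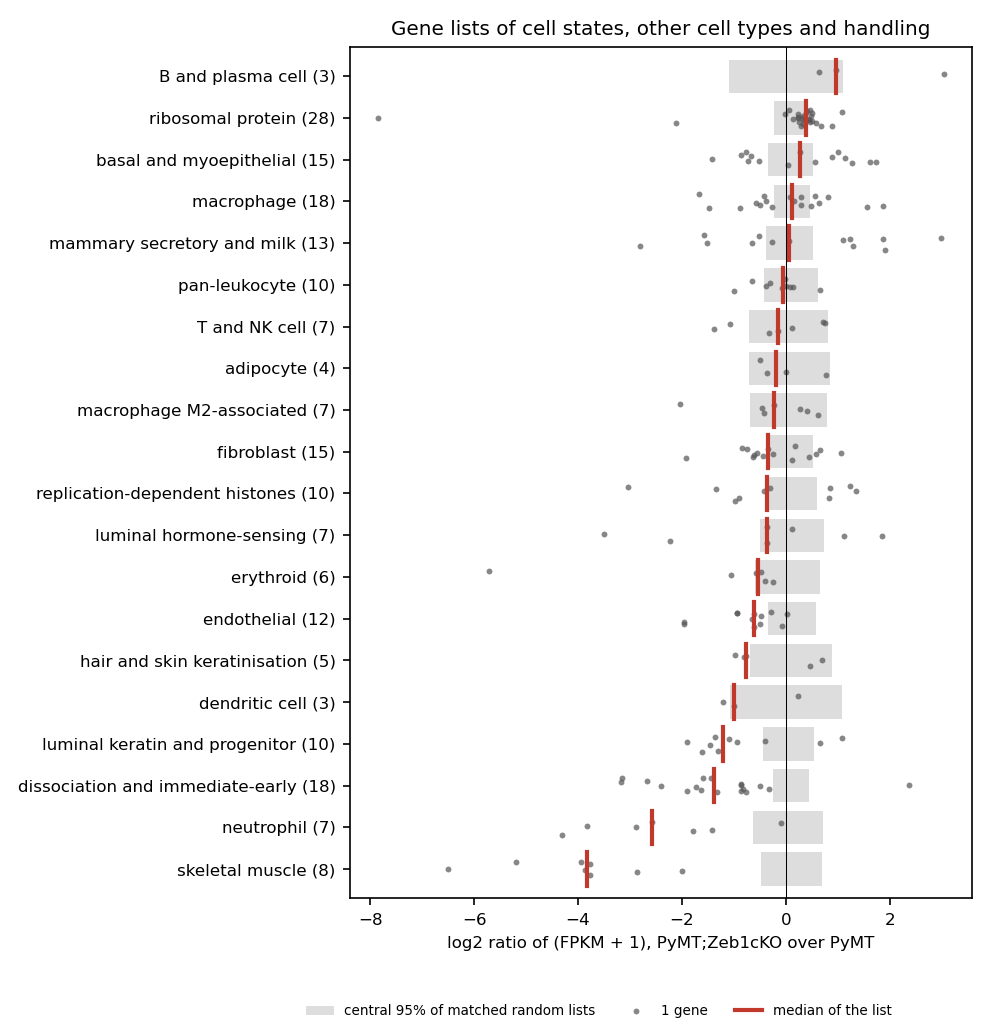
Median log2 ratio (knockout over PyMT library) of each list of cell states, other cell types and handling or RNA-related genes (red line), with its measured members as small points and the central 95% of 10000 matched random lists as a grey bar. Skeletal muscle, at -3.82, neutrophil, at -2.58, and immediate-early genes, at -1.38, lie below their bars, and pan-leukocyte, at -0.05, and macrophage, at 0.12, lie inside theirs.

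The 10 highest and 10 lowest genes included several with few reads in 1 library. Agouti (symbol a, chromosome 2, 154791402 to 155051012), a regulator of coat pigment, went from 10 counts in the PyMT library to 1936 in the knockout library, a log2 ratio of 6.52. The calcium pump gene Atp2a3 (391 and 14362 counts), Acsm1 (12 and 1589), Nmral1 (43 and 1653), Hoxb2 (12 and 1090) and Hoxb5 (6 and 637) were also higher, and so were Dcpp2, Ahcy, Eif3j1 and Dcpp1. Fcgbp, which encodes a mucus-associated protein, went from 50240 counts to 542, a log2 ratio of -6.14, and Acta1, Adm, Ndrg1 and the muscle troponin gene Tnnt3 were among the lowest with Rpl3, Eno1b, Tmem254b, Serpina3n and H2-T22. Of these 20 genes, 9 had non-whole counts and so shared reads with other genes, and their ratios are uncertain. Rpl3 alone went from 23511 to 80 counts, while Rpl3 together with the unnamed model that matches it had a ratio of 1.12 (1.11 to 1.14). Likewise, Ahcy alone had a ratio of 57.2, and 2.4 (2.28 to 2.52) with its copy Gm4737, named outside the rule. Tmem254b had a ratio of 0.00314, against 3.02 (2.89 to 3.15) for the 3 Tmem254 copies together.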

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

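The tests of shared reads, of leukocytes and of muscle were chosen after the results they concern had been seen, and those of library scaling and gene length before. One signal lay outside the comparisons of the report. The 5 unnamed gene models described as immunoglobulin together held 152 estimated counts in the PyMT library and 2993 in the knockout library, a log2 count ratio of 4.32 (95% counting interval 17.0-fold to 23.7-fold), and all 5 were higher in the knockout library.

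The first pattern is the size of the most extreme ratios. Non-whole estimated counts, a mark of reads shared between near-identical copies, were found in 9 of the 20 most extreme genes, or 45.0%, against 16.0% of all genes compared. Shared reads may therefore account for ratios such as those of Rpl3, Ahcy and Tmem254b, which shrank or turned when the copies were summed. The remaining 11 genes, among them agouti, Atp2a3, Fcgbp, Adm and Ndrg1, had whole counts in both libraries, which argues against shared reads for them. For these genes the Zeb1 genotype, untested here, and differences between the animals, such as strain, stay open. Acta1 and Tnnt3, which are among them, are muscle genes and come under the third pattern.

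The second pattern is the higher cell cycle list beside the lower hypoxia, interferon and MHC class I lists. Under the other scalings the smallest of these medians still had a size of 1.42. The scalings differed little, so this outcome was nearly fixed in advance and is not counted as support. A scaling moves all lists the same way, so it alone cannot give higher and lower lists together. Gene length is argued against, since all 4 lists stayed outside the central range when random lists were matched also on length. A smaller share of leukocytes as a whole in the knockout library is argued against as the source of the lower interferon and MHC class I genes, because the pan-leukocyte list had a median of -0.05 with members from -0.99 to 0.66. What stays open is fewer neutrophils, the knockout of Zeb1, and a difference between the sampled tumours or animals. Such a difference could be in size, necrosis, handling or strain, and a single library per group cannot separate these causes. The neutrophil list had a median of -2.58. Selection for EpCAM should remove neutrophils, but leukocyte markers were present in both libraries. Of the neutrophil list, S100a8, S100a9 and Ltf are also made by epithelial cells, and Csf3r had 103 and 91 counts. The lower immediate-early genes, with a median log2 ratio of -1.38, are one sign that handling could have differed, but no test here decides this.

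The third pattern is the lower skeletal muscle list, in which Acta1 (3127 counts against 7) and Myh1 (1636 against 2, named after its values were seen) had the most counts. Reads shared between near-identical copies are argued against, as 7 of the 8 measured genes had whole counts in both libraries. Of 16 other muscle genes that the list lacks, 13 had at least 20 counts in 1 library, and 11 of these (84.6%) were at least 4-fold lower in the knockout library, such as Atp2a1 (1676 counts against 3) and Tcap (202 against 9), while Eno3 (254 and 110) and Tmod4 (12 and 22) were not. Muscle tissue taken along with the PyMT tumour is thus a candidate source. Selection for EpCAM should remove muscle fibres, but markers of other unselected cell types were present in both libraries. Expression of the muscle genes by tumour cells would give the same values and stays open.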

How the results depend on the processing

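No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. The filters on non-whole counts and on the H2 heavy chains were chosen after seeing the data. The 39 list medians gave 351 values under the alternatives, of which 310 kept their direction and their side of the central range, 16 came to stand apart and 10 no longer stood apart. In 3, the sign turned and the call changed: hair and skin keratinisation (0.03) and milk genes (-0.26) without a filter on low values, which adds genes, and histones (0.83) with an FPKM of at least 5, which removes genes. The other 12, from 9 lists, turned in sign while inside the central range: macrophage genes (-0.01 and -0.02) and milk genes (-0.08 each) with TMM factors and the median ratio; luminal hormone-sensing (0.06) and dendritic cell genes (0.03) without a filter; EMT transcription factors (0.52) and M2-associated genes (0.34) with an FPKM of at least 5; M2-associated (0.27), T and NK cell (0.12) and histone genes (0.26) with a mean FPKM of at least 1 and 20 counts; and epithelial genes (0.01) without non-whole counts. The ELR CXC chemokine median no longer stood apart with a pseudocount of 0.1 (-2.26), with TMM factors (-1.39), with random lists matched also on length (-1.43), and with either stricter filter (-2.15), which left Cxcl1 as the single member; the cause was not tested for the former 3. The Zeb1 log2 ratio moved to -1.08 with a pseudocount of 0.1 and to -1.08 with TMM factors, as the main pseudocount exceeds its FPKM. Cxcl1 stayed between -2.91 and -2.07. At 1.5-fold, 3002 genes were higher and 2183 lower, and at 4-fold 211 and 250, by the choice of threshold alone; the other 18 counts stayed within 1.5 times the main ones. Of 684 values for the 171 other named genes, 169 moved beyond the counting interval and no gene past 2-fold changed sign; Psmb10 and Kdr, with log2 ratios of 0.04 and 0.03, did. Depth limits low genes most: Zeb1 and Cxcl1 in the knockout library rest on 38 and 15 counts.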

Other observations

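The genes below were chosen after their values were seen. Hoxb2 to Hoxb7, developmental transcription factors of the Hoxb cluster on chromosome 11, were higher in the knockout library. The 9 listed genes of the cluster held 137 estimated counts in the PyMT library and 4257 in the knockout library, a ratio of 31.5 (95% counting interval 26.6 to 37.6). Hoxb3 was at 0.58 and 19.21 FPKM, Hoxb4 at 0.41 and 11.52, and Hoxb6 at 0.19 and 11.0, whereas Hoxb8 had 17 counts in both and Hoxb9 8 and 17 (ratio 2.16, 0.882 to 5.77). The Hoxa cluster had 67 and 56 counts (ratio 0.848, 0.584 to 1.23), Hoxc 32 and 53 (1.68, 1.06 to 2.69) and Hoxd 106 and 55 (0.526, 0.373 to 0.736). The regulator Foxi3 (0.41 and 15.48 FPKM) was higher in the knockout library too.

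Bhlha15, which encodes the secretory factor Mist1, was at 13.98 and 119.3 FPKM. Jchain, which joins secreted antibodies, went from 7 to 354 counts (ratio 51.3, 24.6 to 129), and Mzb1 from 3 to 21 (ratio 7.1, 2.12 to 37.2). Both stand in the B and plasma cell list of the report, and the unnamed immunoglobulin models were higher as well. The remaining ELR chemokines and the receptor of Cxcl1 were near the limit of detection: Cxcl5 had 20 and 5 counts, Cxcl3 4 and 3, Ppbp 6 and 1, and Cxcr2 20 and 5. Of the macrophage receptors linked to the M2 state, Mrc1 had 101 and 96 counts and Cd163 33 and 16.

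Haemoglobin genes differed in their totals and in which copies were counted. Hbb-bs and Hbb-bt, the adult beta-globin pair of one haplotype, were present in both libraries (4507 and 3474 counts for Hbb-bs). Hbb-b1, of the other haplotype, had 4691 counts in the PyMT library and 7 in the knockout library. Its partner Hbb-b2 had 816 counts in the PyMT library and was not listed in the knockout library. These counts were non-whole, so their split between the copies is uncertain. All 4 adult beta-globin genes together had 10774 and 4130 counts, a ratio of 0.389 (0.375 to 0.403). The alpha-globin gene Hba-a2 also went from 2326 to 37 counts, while both alpha-globin copies together had a ratio of 0.574 (0.558 to 0.591). Among the MHC class II genes, H2-Eb1 had 659 and 13 counts, against 1119 and 989 for H2-Aa and 1769 and 1489 for H2-Ab1. The strain background of the mice was not tested.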
